A study of Mus musculus with 60 samples.

How the data were processed

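Prefrontal cortex was taken from male and female C57BL/6J mice at postnatal day 25, after 3 weeks of vehicle, fluoxetine or lithium given through the mother's milk from day 3 to day 24, per the labels. Mice were wild type (WT) or heterozygous (HT) for the K228E allele of Tbr1. The 60 libraries fall into 12 groups of 5 by genotype, treatment and sex, all taken from the sample titles. RNA-seq libraries were made with a stranded mRNA kit, per the labels' protocols. The labels name no litter, dam or batch, so p-values measure only the spread between these samples. As treatment came through the mother's milk, pups of 1 litter would share it, and if groups hold littermates the p-values are too small.

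The deposited table holds 1 signal per gene and library, which are gene-level read numbers divided by a size factor for each library. Salmon 0.11.2, R 3.6.0 and DESeq2 1.19.11 and genome build GRCm38 are named in the submitters' processing notes, with no role or order. The annotation release and any filter on genes are not given in the sources used here. Each value in the deposited table was a whole multiple of its column's smallest value above 0, at a tolerance of 1e-06, so 100% of values gave whole reads. The totals so recovered ranged from 23930164 to 36515331 reads per library (median 28721151), with size factors from 0.818 to 1.33. Of the 18088 Ensembl identifiers, 18077 matched a symbol and 11 did not, and 20 symbols were shared by more than 1 identifier. Coordinates come from the GENCODE annotation of GRCm38.

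Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, 1 mean per group and all 60 libraries in the fit. Genes at 10 or more in at least 5 libraries were kept, which left 17781 genes. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. P-values were adjusted by Benjamini-Hochberg within each contrast, and genes with an adjusted p below 0.05 were called changed. The contrasts were HT against WT under vehicle, each drug against vehicle in each genotype, the interactions of genotype with each drug, and the interactions of genotype and of each drug with sex, with the sexes averaged and apart. The files hold normalised values, so limma was used in place of the count test that had been set for the case of counts. All tests of limma are two-sided.

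The 36 gene lists of cell types, tissues and pathways were fixed before the data were examined and tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry. Named genes were chosen by a rule fixed before the data were examined. For each contrast averaged over sexes it takes Tbr1, and up to 10 rising and 10 falling genes with the largest fold change among those called. These have a mean of at least 50, the same sign in both sexes and a symbol that is not a predicted gene's. It also takes up to 4 members with the smallest p of each list that passed camera, and the 5 genes with the smallest p where fewer than 5 were called. Where a gene outside this rule is named, that is said. Some genes the rule takes are not reported here. Correlations of fold changes that share vehicle libraries used 100 random splits of those libraries, beside the mean over simulations of unchanged groups.

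The alternatives fixed before the data were examined were other pseudocounts (0.5 and 5), no filter and a stricter filter (mean of at least 100), quantile normalization, a replicate block, no trend, only the compared groups in the fit, library quality weights, striatum and choroid plexus covariates, a fold change of at least 1.2, and leaving out each library in turn. Added after the data had been seen were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, covariates for the olfactory bulb list (its mean log2 value and the same mean on the linear scale, called the bulb covariates), females without the libraries of vehicle males, and leaving out the 2 libraries with the highest olfactory bulb mean. In a further fit each library's smooth trend on GC content and transcript length was removed. The comparison of HT with WT averaged over treatments was also added then.

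The test was checked on simulated counts for the kept genes with 200 changed genes. For HT against WT under vehicle with 17666 genes tested, 91% of genes changed 1.5-fold and 99% of those changed 2.0-fold were called, and 5.47% of calls were false. For fluoxetine in WT females with 17669 genes tested, these shares were 76%, 94% and 5.03%. For the genotype by fluoxetine interaction, with 17661 genes tested, they were 84%, 97% and 3.72%. The simulation drew each gene apart, at a spread estimated from the libraries around their group means. It held no shift shared across genes, such as the one the libraries show along the olfactory bulb list. Among the 120 pairs of libraries of a group, chi-square per degree of freedom was 3.11 or more, so none was taken as a library deposited in duplicate. All columns of the table belong to the 60 samples, and no sample was left out.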

Results

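RNA-seq of prefrontal cortex was available for 60 mice, 5 in each of 12 groups made by Tbr1 genotype (WT or HT for the K228E allele), treatment (vehicle, fluoxetine or lithium until day 24) and sex. Values are size-factor-normalised reads, from libraries of 23930164 to 36515331 reads. The design asks how the heterozygous allele of Tbr1, a T-box transcription factor of deep-layer cortical neurons, changes the cortex of young mice, and how a serotonin reuptake inhibitor and lithium change it in each genotype. Libraries of a group correlated at 0.953 to 0.991. Sex genes matched the label in 60 of 60 libraries, with Xist at 14768 or more in females and at most 248 in males.

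Tbr1 (ENSMUSG00000035033, chromosome 2, 61802930 to 61814114, GRCm38) was read in every library. In vehicle mice it stood at 2195 ± 846 in WT females and 3589 ± 1502 in HT females (SD, n = 5 each), and at 2347 ± 955 in WT males and 4340 ± 837 in HT males. Under fluoxetine it was 3738 ± 91 in WT and 4934 ± 251 in HT females, and 3560 ± 223 in WT and 4432 ± 409 in HT males. Under lithium it was 2970 ± 928 and 4310 ± 655 in WT and HT females, and 3055 ± 587 and 4001 ± 1013 in WT and HT males. The values cannot tell the alleles apart, so they do not check the genotype label.

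**Figure D1:**
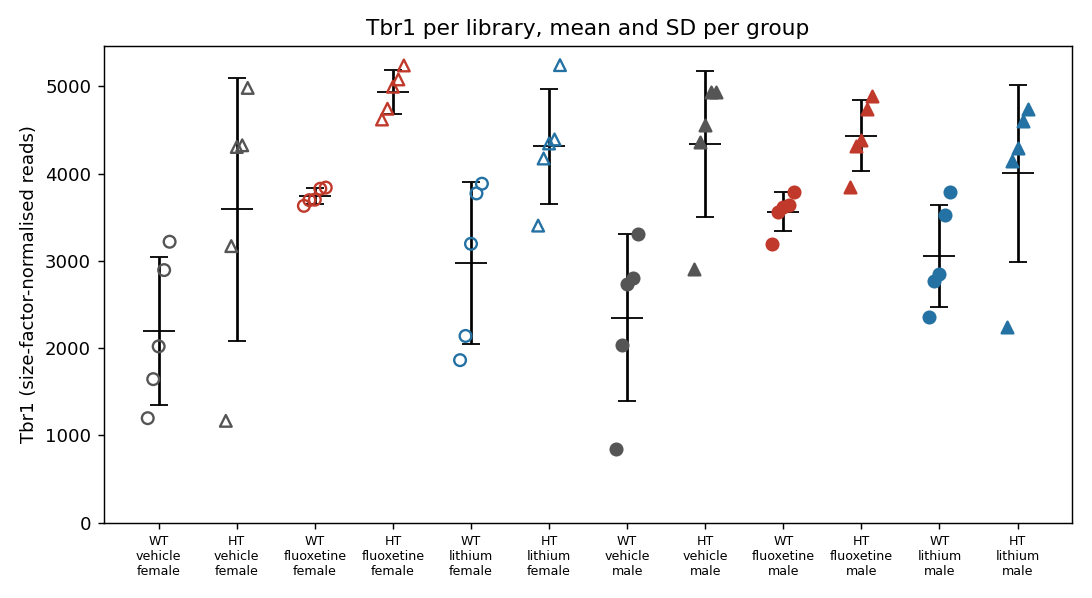
Tbr1 in size-factor-normalised reads for each of the 60 libraries, by group, with the mean and SD of the 5 libraries (WT circles, HT triangles, males filled). Under fluoxetine the WT females lie at 3630 to 3839 and the HT females at 4619 to 5238.

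The libraries differed in markers of the olfactory bulb, which borders the dissected region. The 7 marker genes of this list (Th, Tbx21, Trh, Cdhr1, Doc2g, Eomes and Shisa3) rose and fell together, with correlations across libraries of at least 0.960 between members, and at least 0.919 around the group means. Eomes, a T-box gene of mitral and tufted cells, ranged from 1.10 to 1889 and Cdhr1, a protocadherin of the same cells, from 24.2 to 9772. The mean log2 value of the list was 10.1 ± 0.73 in WT vehicle females and 9.87 ± 0.79 in WT vehicle males, but 5.16 ± 1.39 and 6.10 ± 1.71 in WT mice on fluoxetine (SD, n = 5 each). HT vehicle mice had 8.53 ± 2.12 (females) and 8.50 ± 0.90 (males), and HT mice on fluoxetine 5.34 ± 1.35 and 6.75 ± 1.57. Under lithium the means were 8.66 and 9.0 in WT and 7.35 and 8.08 in HT females and males. The first principal component held 29.5% of the variance.

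**Figure D2:**
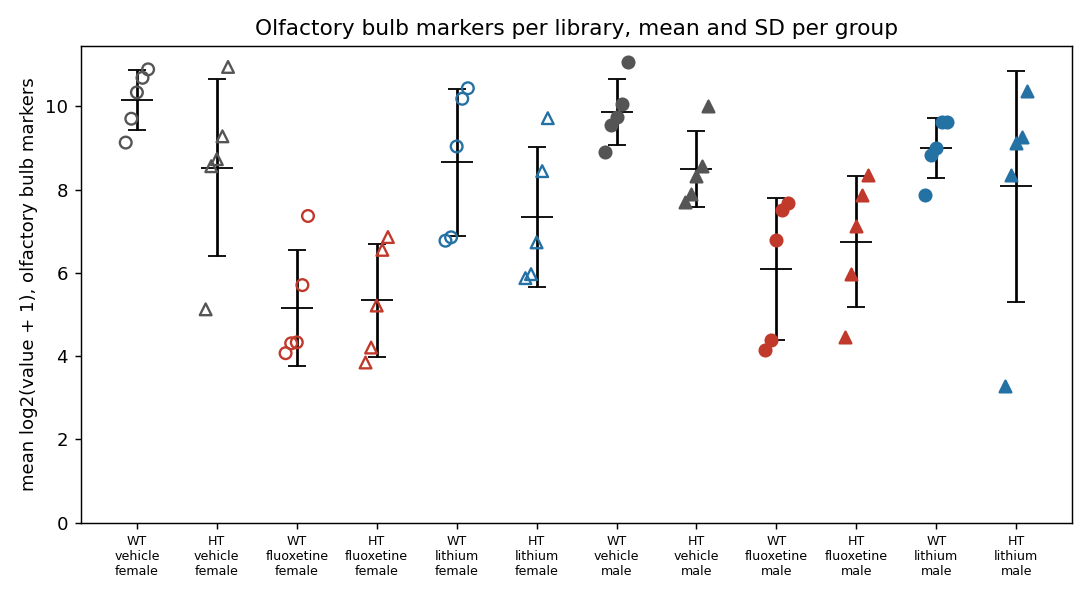
Mean log2(value + 1) of the 7 olfactory bulb markers for each library, by group, with the mean and SD of the 5 libraries (WT circles, HT triangles, males filled). WT vehicle females lie at 9.13 to 10.9 and WT fluoxetine females at 4.07 to 7.37.

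The 10 libraries of vehicle males formed a cluster of their own on the second component (9.46% of the variance), at 17.8 to 47.9 against -32.0 to 12.5 for the other 50. Rps6-ps4, a processed ribosomal protein pseudogene on chromosome 2 (75191073 to 75191822), was at 90.1 to 153 in all 10 and at 0 in all 50 others (it was chosen after its values were seen, and its reads can be shared with its parent gene). Ddx3y, a Y-linked helicase, was at 1668 to 1939 in vehicle males and 1036 to 1413 in the 20 treated males. Mitochondrially encoded genes took 6.58% ± 0.75 of values in WT vehicle males against 4.37% ± 0.27 in WT vehicle females (SD, n = 5 each). No label names a batch. Every vehicle male is in this cluster and no treated male is, so for males the cluster and the treatment cannot be told apart. Gene counts in females are therefore given beside the averaged ones, as are female values for some of the named genes. A drug effect given without a female value is an average over both sexes that includes the cluster. HT and WT vehicle males are in the cluster alike.

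**Figure D3:**
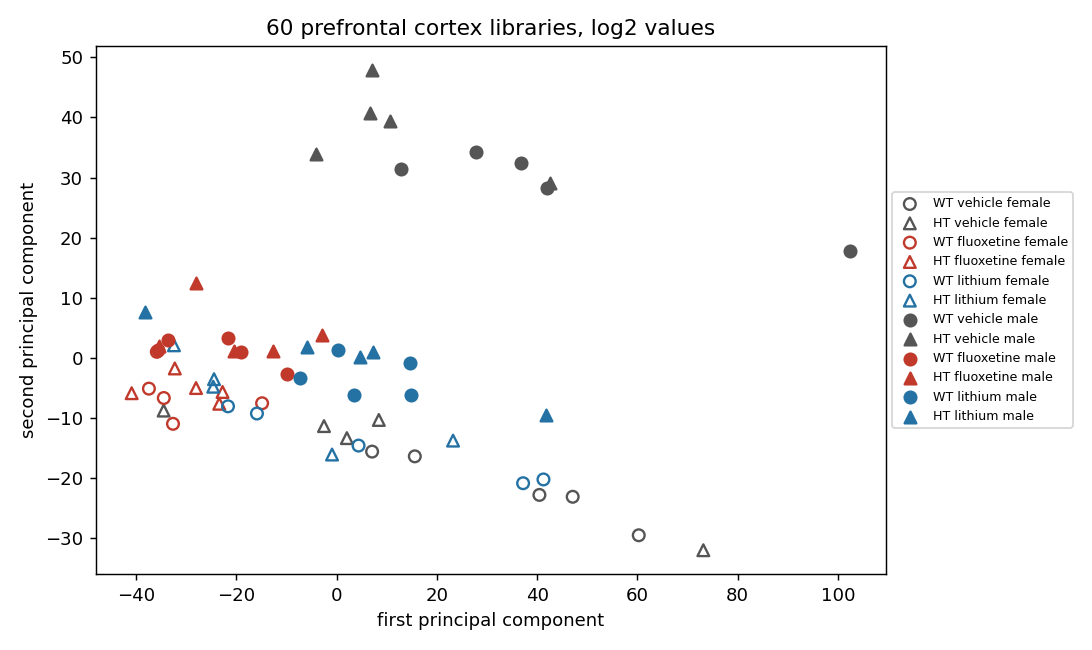
First and second principal components of the log2 values of the 60 libraries (arbitrary units), coloured by treatment (WT circles, HT triangles, males filled). The 10 vehicle males lie at 17.8 or more on the second component and the other 50 libraries at 12.5 or less.

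HT against WT under vehicle asks what the allele does without a drug. With limma, 6 genes passed, 1 higher and 5 lower in HT mice. Cebpd, a stress- and cytokine-induced transcription factor, fell by 0.70 (log2; SE 0.14, adjusted p = 0.028), and Trpc7, a calcium-permeable cation channel, fell by 0.47 (SE 0.09, adjusted p = 0.028). Shisa6, an AMPA receptor auxiliary subunit, fell by 0.62, and Fam43a fell by 0.39. Trp73, named though its mean of 33.6 is below the minimum of the naming rule, fell by 1.62 (SE 0.27, adjusted p = 0.0049). Car15, a carbonic anhydrase, rose by 0.46 (SE 0.10, adjusted p = 0.0499). Tbr1 itself was 0.82 higher in HT (SE 0.19), with adjusted p = 0.063. All 6 called genes had the same sign in both sexes, which selection by the average over the sexes partly fixes in advance. The count depended on single libraries. It was 6275 without replicate 1 of the HT vehicle females, 3030 without replicate 2 of the HT vehicle males, 3688 without replicate 1 of the WT vehicle males, 3123 without replicate 4 of the WT vehicle females, 14 without replicate 5 of the WT vehicle females or replicate 2 of the WT vehicle males, and 1 to 3 without replicate 2, 3, 4 or 5 of the HT vehicle females, 1, 3, 4 or 5 of the HT vehicle males, 1, 2 or 3 of the WT vehicle females or 4 of the WT vehicle males. Tbr1 passed without replicate 1 of the HT vehicle females (1.004, adjusted p = 0.0013), 2 of the HT vehicle males (0.89), 4 of the WT vehicle females (0.90) or 1 of the WT vehicle males (0.90). With the bulb covariates 2 genes were called, Trp73 (-1.02) and 5330416C01Rik (-0.89), and Tbr1 was at 0.22 (adjusted p = 0.183). DESeq2 called 1583 genes, Tbr1 among them but only 2 of these 6, edgeR called 9, with 5 of the 6, and limma with library quality weights 6987.

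Of the 36 lists, 14 passed camera for this contrast, 11 upward and 3 downward, though no single member of any passed over all genes tested. Excitatory synapse genes were higher as a list (28 measured, median 0.20, camera adjusted p = 0.00048), with 15 higher and 2 lower when adjusted over the list alone. Grm5, a metabotropic glutamate receptor, was at 0.24 and the AMPA receptor subunits Gria1 and Gria4 were at -0.17 each. Presynaptic release genes such as Rims1 (0.46) and Syp (0.21) had a median of 0.18 over 22 members (adjusted p = 0.00048). The olfactory bulb list was lower (7 measured, median -1.47, adjusted p = 0.0088), and the striatum list was higher (12 measured, median 0.66, adjusted p = 0.0069), with Ppp1r1b at 0.76. The mean log2 value of that list was 10.02 and 9.86 in replicates 4 and 5 of the HT vehicle males and at most 8.99 in the other vehicle libraries. Activity-regulated genes were lower (20 measured, median -0.30, adjusted p = 0.018), with Npas4 at -0.97, Btg2 at -0.81 and Fos at -0.78. Upper layer neuron, oligodendrocyte, inhibitory synapse, thyroid hormone, cholesterol, endoplasmic reticulum stress, nuclear-encoded oxidative phosphorylation and mitochondrially encoded lists were also higher, and the meninges list lower. Adjusted over the list alone, higher and lower members numbered 6 and 0 for presynaptic release, 0 and 7 for olfactory bulb, 5 and 0 for striatum, 2 and 4 for activity-regulated, 4 and 1 for upper layer, 7 and 3 for inhibitory synapse, 4 and 0 for thyroid hormone, 2 and 0 for cholesterol and 1 and 0 for endoplasmic reticulum stress genes, and 0 and 0 for the other 4. None of the 14 held with an estimated correlation, where the adjusted p was 0.746 for most and 0.818 for the oligodendrocyte list. With the bulb covariates the synaptic lists turned, with a median of -0.026 for excitatory synapse and -0.043 for presynaptic release genes, Rims1 at -0.044 and Syp at -0.028, and the activity-regulated list had a median of -0.21 (camera adjusted p = 0.021). Of the 14 lists, 5 passed in the same direction with those covariates.

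Fluoxetine in WT mice asks what the drug does in the absence of the allele. Of the 10 genes that fell furthest among those named, 5 belonged to the list of olfactory bulb markers. Eomes (-5.47, SE 0.85, adjusted p = 3.82e-07), Tbx21 (-4.75), Shisa3 (-4.63), Doc2g (-4.43) and Cdhr1 (-4.21) are members of the list. Ms4a15 (-5.0), S100a5 (-4.7), Frmd7 (-4.63), Scgn (-4.6) and Dnah11 (-4.44) are not in the list, but none of them was still called with the bulb covariates. Rises included Gdf1 (4.35, SE 1.58), Tfap2d (2.33), the sodium channel subunit Scn4b (1.99), Thbs4 (1.73), Npsr1 (1.64), Rsc1a1 (1.63), Igfn1 (1.51), Sebox (1.44) and the pseudogene Trmt112-ps2 (1.43). Gdf1 was not called in females (3.15, adjusted p = 0.259) or with the bulb covariates (3.34, adjusted p = 0.227). In females Rsc1a1 was at 0.12 (adjusted p = 0.92) and Trmt112-ps2 at 0.30 (adjusted p = 0.718), against 3.13 and 2.57 in males, where vehicle and cluster coincide. Tbr1 rose by 0.80 (SE 0.19, adjusted p = 0.00036), a call lost with striatum and choroid plexus covariates (0.24, adjusted p = 0.389), with which 5518 genes passed for this contrast and 12 in females.

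Of the lists, 6 passed camera for fluoxetine in WT. All 7 olfactory bulb markers fell (median -4.43, camera adjusted p = 0.0010). Presynaptic release genes rose in 19 of 22 and fell in 1 (median 0.41, adjusted p = 7.08e-05), with the vesicle GTPase Rab3a at 0.34. Excitatory synapse genes rose in 20 of 28 and fell in 3 (median 0.36, adjusted p = 0.0047), among them the NMDA receptor subunit Grin1 (0.38) and the AMPA receptor regulator Cacng8 (0.57), while Gria4 fell by 0.32. Microglial genes rose in 9 of 12 (median 0.24, adjusted p = 0.0047), with Trem2 at 0.47 and Csf1r at 0.41. Nuclear-encoded oxidative phosphorylation genes rose in 44 of 80 and fell in 7 (median 0.13, adjusted p = 0.00012), led by Ndufs7 (0.35), and meningeal genes fell in 7 of 10, with the collagen gene Col3a1 at -0.82 (median of the list -0.42, adjusted p = 0.038). The choroid plexus list did not pass (7 measured, 4 fell, median -0.84, adjusted p = 0.194). The counts adjusted over the list alone were the same for each of these 7 lists. None of the 6 held with an estimated correlation (adjusted p = 0.86 for each), and with the bulb covariates 2 of the 6 passed in the same direction, microglia and oxidative phosphorylation. In females the oxidative phosphorylation list had a median of 0.044 (camera adjusted p = 0.343), with Ndufs7 at 0.047, and Cacng8 was at 0.29, Grin1 at 0.22, Gria4 at -0.19, Trem2 at 0.30 and Csf1r at 0.23. Of the 11 lists that passed camera in females, 0 passed in the same direction with the bulb covariates.

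With limma, 11239 genes passed for fluoxetine in WT, 5639 higher and 5600 lower, and 10316 in males alone. In females, outside the vehicle male cluster, 7084 passed (3710 higher, 3374 lower), and 4 with the bulb covariates. These were Traf3 (-0.40, SE 0.07), Castor2 (-0.30, SE 0.05) and Fsd1 (-0.24, SE 0.04), which fell, and Gng8 (1.497, SE 0.31), which rose. Over both sexes with those covariates, 4258 genes passed, and of the 9 genes listed as rises Thbs4 (1.32) alone was still called. Tfap2d was at 1.25, Rsc1a1 at 1.54, Trmt112-ps2 at 0.94, Npsr1 at 0.20, Igfn1 at 0.23, S100a5 at -0.37, Rab3a at 0.087 and Col3a1 at -0.39, none called. Tbr1 (-0.19), Scn4b (-0.27), Sebox (-0.0074), Ms4a15 (0.27), Frmd7 (0.12), Scgn (0.19) and Dnah11 (0.050) turned. Of these, Tbr1 was called as lower by limma with the covariates (SE 0.063, adjusted p = 0.024). Members of the list behind the covariates balance around 0 by construction, so the signs of Doc2g (0.20) and Cdhr1 (0.37) carry no evidence here. The female count was 4298 without replicate 3 of the WT vehicle females.

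In HT mice on fluoxetine olfactory bulb markers fell too, among them Eomes (-2.98, SE 0.85, adjusted p = 0.0044), Tbx21 (-2.78), Shisa3 (-2.55), Cdhr1 (-2.42) and Doc2g (-2.42). Scgn (-2.82), Ms4a15 (-2.73) and Frmd7 (-2.71) fell as well, as did the pseudogenes Rpl15-ps3 (-3.58) and Ptges3-ps (-2.86). Depp1, a FOXO-induced gene, rose by 1.42 (SE 0.19, adjusted p = 1e-07), Alox12b by 0.91, Usp43 by 0.73, Clec18a by 0.71 and Map3k21 by 0.69, beside the pseudogenes Tmem181c-ps (1.39) and Tmem181b-ps (0.67). In females Depp1 was at 0.79 (adjusted p = 0.156) and Ptges3-ps at -1.32 (adjusted p = 0.617). The other genes named above are given over both sexes only, so their values include the vehicle male cluster. Tbr1 was 0.33 higher (SE 0.19, adjusted p = 0.163).

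In HT mice 7 lists passed camera for fluoxetine. All 7 olfactory bulb markers fell (median -2.42, camera adjusted p = 0.0066), and presynaptic release genes rose in 14 of 22 and fell in 1 (median 0.20, adjusted p = 0.0016), among them Nrxn2 (0.26) and Sv2a (0.14). Microglial genes rose in 7 of 12 (median 0.19, adjusted p = 0.0066). Genes of the endoplasmic reticulum stress list fell in 8 of 17 and rose in 2 (median -0.12, adjusted p = 0.02), with Dnajc3 at -0.27 and Hspa5 at -0.32. Mitochondrially encoded genes fell in 10 of 13 (median -0.22, adjusted p = 0.0016), among them mt-Nd1 (-0.23) and mt-Nd6 (-0.23). Ribosomal protein genes rose in 28 of 85 and fell in 7 (median 0.057, adjusted p = 0.014), with Rpl37 at 0.35, and nuclear-encoded oxidative phosphorylation genes rose in 37 of 80 and fell in 5 (median 0.094, adjusted p = 0.00092), with Ndufs7 at 0.26. Adjusted over the list alone, 38 of the last list rose and 8 fell, 11 mitochondrially encoded genes fell, and the other counts were the same. None held with an estimated correlation (adjusted p = 0.903 for each), and 4 of the 7 passed in the same direction with the bulb covariates. In females the ribosomal protein list was lower (median -0.11, camera adjusted p = 1.01e-07, adjusted p = 0.697 with an estimated correlation, 0 of 85 called over all genes tested or over the list alone). There mt-Nd1 was at 0.13, mt-Nd6 at 0.17, Rpl37 at 0.0055, Ndufs7 at 0.012, Nrxn2 at 0.10, Sv2a at 0.026 and Dnajc3 at -0.067, and with the bulb covariates Scgn was at -0.095, Ms4a15 at 0.35 and Frmd7 at -0.025 over both sexes, and Rpl15-ps3 (-3.04) and Ptges3-ps (-2.47) were not called. List members there, such as Eomes (0.068), Cdhr1 (0.17) and Doc2g (0.18), balance around 0 by construction.

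With limma, 7249 genes passed for fluoxetine in HT (3590 higher, 3659 lower), and 7356 in males. Once a GC and length trend was removed, 3396 of 7248 and 2123 of 7355 in males were still called. In HT females 0 passed with limma (4063 at an unadjusted p below 0.05), 0 with edgeR and 388 with DESeq2, and with limma 1027 without replicate 4 and 1 without replicate 2 of the HT vehicle females. The smallest adjusted p was 0.107. Of the 7249 genes, 83.8% had the same sign in females and males, a share partly fixed in advance by selection on the average over the sexes. Their median absolute change was 0.12 in females and 0.34 in males.

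In WT mice on lithium, genes that neurons switch on with activity were lower than in vehicle mice. The transcription factor genes Atf3 (-1.90, SE 0.42, adjusted p = 0.00026), Fosb (-1.25, SE 0.24, adjusted p = 4.8e-05) and Nr4a2 (-1.07, SE 0.28) fell, as did Apold1 (-1.18). As a list, activity-regulated genes fell in 14 of 20 over all genes tested and in 14 of 20 adjusted over the list alone (median -0.63, camera adjusted p = 0.00034, adjusted p = 0.965 with an estimated correlation), with Fosl2 at -1.05, Fos at -0.997 and Nr4a3 at -0.91. Other genes that fell were Trdn (-1.49), Cpa6 (-1.27), the glial fatty acid binding protein gene Fabp7 (-1.20), the R-spondin receptor Lgr5 (-1.18), Tex15 (-1.10) and Aplnr (-1.09). Rises included Thbs4 (1.66, SE 0.33), Trmt112-ps2 (1.43), Scn4b (1.43), Kirrel2 (1.06), Wnt2 (1.03), Map3k6 (1.02, SE 0.15, adjusted p = 1e-06), Mc4r, Nxph3 and Ppp1r1b (1.01 each). Of these, Ppp1r1b belongs to the striatum list, whose mean was 10.4 and 10.3 in replicate 2 of the WT lithium females and males and at most 8.06 in the other 8 of those groups. Once the bulb covariates were in the fit, Scn4b (0.12), Wnt2 (0.013), Mc4r (0.17), Nxph3 (0.083), Ppp1r1b (0.42), Cpa6 (-0.31), Fabp7 (-0.33) and Tex15 (-0.29) were not called. Atf3 (-0.96), Fosb (-0.78), Apold1 (-0.56), Fosl2 (-0.57), Trdn (-0.43), Lgr5 (-0.255) and Kirrel2 (0.64) were called at smaller values. In females Trmt112-ps2 was at 0.30 (adjusted p = 0.832), Nr4a2 at -0.54 (adjusted p = 0.531) and Tex15 at -0.71 (adjusted p = 0.535). Tbr1 rose by 0.48 (SE 0.19, adjusted p = 0.038), and this call was lost with only the compared groups in the fit (0.48), with edgeR (0.41) and in females (0.47, adjusted p = 0.469), while the value was -0.080 with the bulb covariates. It was also lost without replicate 2, 4 or 5 of the WT lithium females, 2 or 4 of the WT lithium males, 1, 2 or 3 of the WT vehicle females or 2 or 4 of the WT vehicle males, with 0.32 the lowest value.

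Apart from the activity-regulated genes, 6 lists passed camera for lithium in WT. Presynaptic release genes rose in 14 of 22 and fell in 1 (median 0.24, adjusted p = 0.00028), with Bsn at 0.52 and Unc13a at 0.33. Excitatory synapse genes rose in 14 of 28 and fell in 3 (median 0.23, adjusted p = 0.032), with Agap2 at 0.29. Microglial genes rose in 7 of 12 (median 0.21, adjusted p = 0.024), with Tmem119 at 0.35, and the blood list rose in 5 of 5 (median 0.58, adjusted p = 0.024), with the haemoglobin genes Hba-a2 at 0.76 and Hbb-bs at 0.497. Nuclear-encoded oxidative phosphorylation genes rose in 41 of 80 and fell in 6 (median 0.098, adjusted p = 0.00027), and mitochondrially encoded genes fell in 5 of 13 (median -0.16, adjusted p = 0.041). Adjusted over the list alone, 16 presynaptic genes rose, 1 microglial gene fell, 8 oxidative phosphorylation genes fell and 7 mitochondrially encoded genes fell, with the other counts the same. In females Nrxn2 was at -0.066, Ndufs7 at -0.019, mt-Nd4l at 0.0098 and mt-Atp6 at 0.015, against 0.24, 0.28, -0.42 and -0.82 over both sexes. None of the 7 lists held with an estimated correlation (adjusted p = 0.965 for each), and 3 passed in the same direction with the bulb covariates, the activity-regulated, oxidative phosphorylation and mitochondrially encoded ones, while Hbb-bs was no longer called (0.30, adjusted p = 0.136). In females Hba-a2 was at 0.23 and Hbb-bs at 0.19 (blood list median 0.21, camera adjusted p = 0.303), Bsn at 0.29, Unc13a at 0.15, Agap2 at 0.058 and Tmem119 at 0.18. The mitochondrially encoded list was higher in females (median 0.14, camera adjusted p = 0.011, adjusted p = 0.784 with an estimated correlation), with 0 of 13 called over all genes tested and 1 over the list alone.

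With limma, 7585 genes passed for lithium in WT (3873 higher, 3712 lower) and 8571 in males, but 1 in females. Once a GC and length trend was removed, 3614 of 7583 and 3103 of 8568 in males were still called. The gene in females was Nkd1, a Wnt-induced antagonist of Wnt signalling, which fell by 0.41 (SE 0.07, adjusted p = 0.024). The female count was 49 without replicate 3 of the WT lithium females, and 0 without replicate 2, 4 or 5 of that group or replicate 1, 3 or 5 of the WT vehicle females. Among females the activity-regulated list had a median of -0.63 (camera adjusted p = 6.25e-07, adjusted p = 0.644 with an estimated correlation), with 9 of 20 lower when adjusted over the list alone. With the bulb covariates that median was -0.46, and 11 genes were called in females, all lower, among them Nkd1 (-0.37, SE 0.08), the clock repressor Nr1d1 (-0.37, SE 0.07) and the synaptic adhesion gene Slitrk1 (-0.22, SE 0.04).

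In HT mice on lithium Atf3 (-1.14, SE 0.42, adjusted p = 0.04) and Nr4a2 (-0.92, SE 0.28) fell. Other genes that fell were the pseudogenes Ptges3-ps (-3.07) and Eif4a-ps4 (-1.88), Tnfaip6 (-0.72), Nuf2 (-0.70), Tmem252 (-0.69), Trim59 (-0.59), Tiparp (-0.59) and Smco3 (-0.56). Etnppl, an astrocytic phospholyase, rose by 0.83 (SE 0.26, adjusted p = 0.016), Cited4 by 0.64, Nphs1 by 0.63, Kirrel2 by 0.60, Hba-a1 by 0.58, the adrenergic receptor Adra1d by 0.58 (SE 0.10, adjusted p = 3.63e-05), Hba-a2 by 0.56, Trim72 by 0.56, Pla2g3 by 0.54 and Esrrb by 0.51. In females Cited4 was at 0.40, Kirrel2 at 0.39, Hba-a1 at 0.19, Adra1d at 0.34, Hba-a2 at 0.15, Trim72 at 0.19, Nr4a2 at -0.60, Nuf2 at -0.39 and Trim59 at -0.25. The genes named above without a female value are given over both sexes only, so their values include the vehicle male cluster. Tbr1 was 0.14 higher (SE 0.19, adjusted p = 0.664), at 0.41 in females (adjusted p = 0.556) and -0.14 in males (adjusted p = 0.733). It was at -0.048 without replicate 1 of the HT vehicle females and 0.025 with the bulb covariates.

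In HT mice 4 lists passed camera for lithium. Activity-regulated genes fell in 3 of 20 (median -0.31, camera adjusted p = 0.0485), which were Junb (-0.48), Klf4 (-0.29) and Nr4a3 (-0.53), and in 0 of 20 when adjusted over the list alone. Presynaptic release genes rose in 7 of 22, and in 8 adjusted over the list alone (median 0.15, adjusted p = 0.031), with Sv2a at 0.16 and Syn2 at 0.19. Nuclear-encoded oxidative phosphorylation genes rose in 34 of 80 and fell in 3 (median 0.10, adjusted p = 5.39e-07), led by Ndufa2 (0.37), and adjusted over the list alone 38 rose and 4 fell. Mitochondrially encoded genes fell in 7 of 13, and in 9 adjusted over the list alone (median -0.20, adjusted p = 0.0024), with mt-Atp6 at -0.68 and mt-Nd6 at -0.23, but at 0.61 and 0.23 in females, where Nrxn2 was at -0.044, Ndufs7 at -0.016, Ndufa2 at 0.061, Sv2a at 0.040 and Nr4a3 at -0.32. None held with an estimated correlation (adjusted p = 0.954 for each), and 3 of the 4 passed in the same direction with the bulb covariates, while Nr4a3 was no longer called (-0.48, adjusted p = 0.0545). In females the mitochondrially encoded list was higher (median 0.18, camera adjusted p = 0.00027, adjusted p = 0.636 with an estimated correlation), with 0 of 13 called over all genes tested or over the list alone.

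With limma, 4128 genes passed for lithium in HT (2241 higher, 1887 lower), 6559 in males and 3 in females. Once a GC and length trend was removed, 740 of 4128 were still called, and 1512 of 6559 in males. The 3 in females were Castor2, a gene of the arginine-sensing branch of the mTORC1 pathway (0.34, SE 0.06, adjusted p = 0.0024), Stk4, a Hippo pathway kinase (0.23, SE 0.05), and Zfp322a (0.22, SE 0.04), all higher. The count was 1 without any of replicates 2 to 5 of the HT lithium females or without replicate 2 or 3 of the HT vehicle females. With the bulb covariates 4 genes were called in females, Castor2 (0.30), Txndc16 (0.20) and Stk4 (0.19), which rose, and Nr1d1 (-0.36), which fell. With only the compared groups in the fit 2720 genes passed for both sexes, and 0 in females.

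The interaction of genotype with fluoxetine asks whether HT mice respond otherwise than WT mice. With limma 0 genes passed (2628 at an unadjusted p below 0.05), 0 with edgeR and 2 with DESeq2. The smallest p-values belonged to Folr2 (1.46, SE 0.32), R3hcc1l (0.24, SE 0.06), the zinc finger gene Tshz2 (0.44, SE 0.11), Hspa1l (1.28, SE 0.31) and Car15 (-0.53, SE 0.14), none of which passed (adjusted p = 0.332 each). Tbr1 was at -0.47 (SE 0.27, adjusted p = 0.348). Library quality weights gave 5139 genes, with Tbr1 at -0.53 (adjusted p = 0.0071). By camera 10 lists passed over both sexes, but 0 in females without the libraries of vehicle males. The activity-regulated list was higher in the interaction (20 measured, median 0.45, adjusted p = 0.00036), with Npas4 at 1.15 and Fosb and Fos at 0.94 each, and 2 of 20 higher when adjusted over the list alone, where no other list had any member called. The oligodendrocyte list was lower (15 measured, median -0.42, adjusted p = 0.0048), with Opalin at -0.69 and Mal at -0.63, and both lists passed with the bulb covariates too. The olfactory bulb (median 1.98) and meninges (0.32) lists were also higher, and the striatum (-0.61), excitatory synapse (-0.18), presynaptic release (-0.18), thyroid hormone (-0.20), oxidative phosphorylation (-0.047) and mitochondrially encoded (-0.12) lists lower. No list held with an estimated correlation (adjusted p = 0.692 or more).

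For the interaction of genotype with lithium 0 genes passed with limma (711 at an unadjusted p below 0.05), 0 with edgeR and 1 with DESeq2. The smallest p-values belonged to Spata3 (-1.61, SE 0.37), Zfp64 (-0.23, SE 0.06), Coil (0.23, SE 0.06), Map3k6 (-0.87, SE 0.22) and Pthlh (-0.62, SE 0.16), with adjusted p = 0.812 each, and Tbr1 was at -0.35 (SE 0.27). By camera 7 lists passed, and 5 in females without the libraries of vehicle males. Layer 6 and subplate genes were lower (12 measured, median -0.18, adjusted p = 0.024), with the deep-layer receptor Ntsr1 at -0.36 and Cplx3 at -0.45. The striatum (median -0.73), oligodendrocyte (-0.40), glucocorticoid (-0.23), excitatory synapse (-0.11) and presynaptic release (-0.11) lists were lower and the activity-regulated list higher (0.24, with Egr3 at 0.44), with 0 members called over all genes tested or over the list alone. The mean log2 value of the striatum list was 10.4 and 10.3 in replicate 2 of the WT lithium females and males, 10.2 in replicate 1 of the HT lithium females, and 10.02 and 9.86 in the HT vehicle males above, against at most 8.99 in the other vehicle and lithium libraries, and its member Pde10a was at -0.67 over both sexes but 0.12 in females. With an estimated correlation the adjusted p was 0.675 for the glucocorticoid list and 0.88 for the others, and 5 of the 7 passed in the same direction with the bulb covariates.

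The sexes differed in vehicle mice and hardly in treated mice. Males against females gave 7115 genes in WT and 6887 in HT vehicle mice with limma, but 11 and 10 under fluoxetine and 9 and 10 under lithium. The interactions with sex gave 7029 genes for fluoxetine and 7251 for lithium. The counts in vehicle mice and for these interactions involve the cluster of vehicle males, and once a GC and length trend was removed 1203 of 7114 and 1393 of 6886 were still called in WT and HT vehicle mice. The genotype by sex interaction under vehicle, inside which both genotypes share the cluster, gave 0 genes with limma (291 at an unadjusted p below 0.05), 0 with edgeR and 7 with DESeq2, and 1 with limma without replicate 2 of the HT vehicle males, 2 of the WT vehicle females or 1 of the WT vehicle males. HT against WT under vehicle gave 0 genes in females (1347 unadjusted, 0 with edgeR, 4 with DESeq2) and 0 in males (4151 unadjusted, 0 with edgeR, 3 with DESeq2). In females it gave 247 without replicate 1 of the HT vehicle females, and in males 1 without replicate 2 of the HT or replicate 1 of the WT vehicle males. Of the genes called over both sexes for a drug, those with the same sign in females and males made up 90.3% for fluoxetine in WT, 80.8% for lithium in WT and 66.3% for lithium in HT. Of the called genes, 6085, 1 and 2 were called in females. As they were selected by the average over the sexes, the shared sign is partly fixed in advance. Their median absolute change was 0.27 in females and 0.42 in males for fluoxetine in WT. It was 0.091 and 0.38 for lithium in WT, and 0.058 and 0.32 for lithium in HT.

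Fold changes of the contrasts were compared across 17781 genes, which are not independent replicates. The 6 correlations were descriptive. Fluoxetine effects in WT and HT, which share no library, correlated at 0.83, and lithium effects at 0.64, against -0.0050 and -0.0059 in simulated unchanged groups, which hold no vehicle male cluster. In females, outside the cluster, these were 0.78 and 0.49. The simulation drew each gene apart and held no shift shared across genes, such as the one along the olfactory bulb list. Unchanged groups that differ along such a shift could correlate strongly in either direction. The simulated values in this paragraph therefore show only what shared libraries give on average, and do not measure chance. Higher genes for fluoxetine numbered 3203 in common to both genotypes (1139 for independent lists) and lower ones 3225 (1152), and for lithium 1894 (488) and 1616 (394), calls over both sexes that include the cluster in both genotypes. With the vehicle libraries split, fluoxetine and lithium effects correlated at 0.64 ± 0.09 (SD over 100 splits) in WT and 0.38 ± 0.16 in HT. With all libraries these were 0.82 and 0.68, beside 0.50 and 0.50 in unchanged groups, and the covariance exceeded the simulated one by 0.117 and 0.036. The genotype effect and the fluoxetine effect in HT correlated at 0.45 ± 0.18 (0.45 with all libraries, -0.51 in unchanged groups, covariance difference 0.052), and the genotype and lithium effects at 0.24 ± 0.22 (0.15, -0.51 and 0.023). With the bulb covariates these last 2 were 0.0078 and -0.012. In females with those covariates, fluoxetine effects in WT and HT correlated at 0.38 and lithium effects at 0.17.

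Tbr1 was lower in libraries with more olfactory bulb signal. On the log2 scale and around the group means, Pearson's r was -0.586 and Spearman's rho -0.659 over 60 libraries (two-sided permutation test within groups, p = 1e-05 for each, the smallest 100000 resamples can give), and r was -0.593 without the 2 libraries farthest from the median. Within the 10 vehicle males r was -0.86 (p = 0.00029 by the same permutation test) and rho -0.83 (p = 0.0021), with r at -0.689 without the 2 farthest. Within the other 50 libraries r was -0.592 (p = 0.00028) and rho -0.647 (p = 1e-05), with r at -0.584. For these 3 sets of libraries the adjusted p-values of r were 3e-05, 0.00029 and 0.00029, and of rho 1.5e-05, 0.00212 and 1.5e-05.

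**Figure D4:**
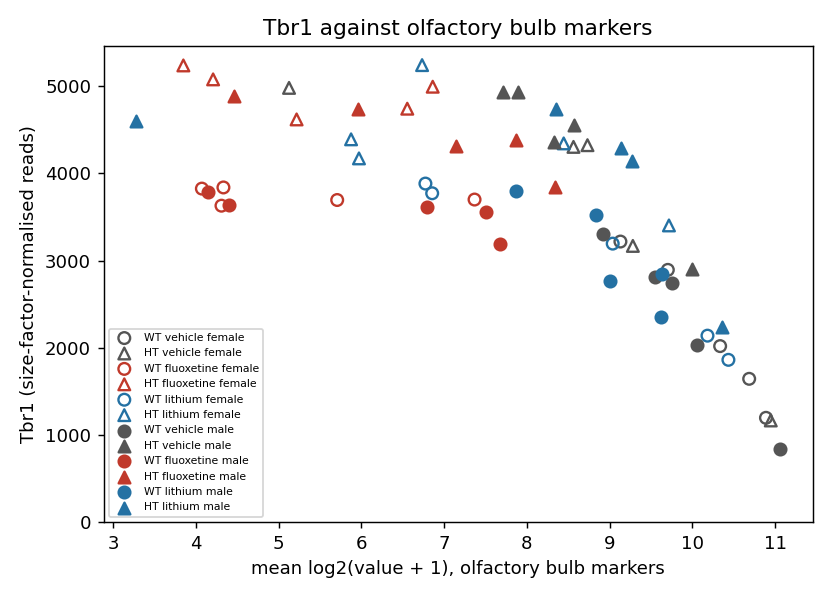
Tbr1 in size-factor-normalised reads against the mean log2(value + 1) of the 7 olfactory bulb markers for the 60 libraries, coloured by treatment (WT circles, HT triangles, males filled). Around the group means the correlation of log2 Tbr1 with the marker mean is -0.586.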

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

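The tests of an action of both drugs on males, the correlations beside the -0.684, of fluoxetine at the same tissue make-up and of Tbr1 with the bulb covariates, and all values with those covariates, and the count of genes still called once a GC and length trend was removed, were chosen after the result was seen.

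Drug effects differed between the sexes by the interaction test for 7029 genes with fluoxetine and 7251 with lithium, and both counts rest on the vehicle males' libraries, which stand apart. Removing each library's trend on GC content and transcript length (17770 genes, 99.9% of those tested) left 6488 of 10312 genes called for fluoxetine in WT males, between the limits set for and against such a trend. In comparisons for which no limit was set, it left 2123 of 7355 for fluoxetine in HT males, 3103 of 8568 for lithium in WT males and 1512 of 6559 for lithium in HT males. It left 1203 of 7114 genes called between the sexes in vehicle mice in WT and 1393 of 6886 in HT, and 1349 of 7028 and 1379 of 7250 for the interactions of sex with fluoxetine and lithium. A GC trend thus stays open for much of the pattern. Across genes, the sex difference in vehicle mice correlated with GC content at -0.556 in WT and -0.512 in HT. With log2 transcript length it correlated at 0.041 and 0.073, which argues against a linear length trend as the main cause of that difference. No limit was set for these correlations. Across genes, the male minus female difference in WT vehicle mice correlated at -0.684 with the mean drug effect in HT males, past the -0.5 set for a library or processing batch shared by the vehicle males, against 0.071 in HT females, while HT vehicle mice against WT males, for which no limit was set, gave -0.45. Such a batch cannot be told apart from an action of both drugs on males that erases a baseline difference of the sexes, because all vehicle males and no treated male lie in the cluster, and both would give such a correlation and 646.8 times as many genes called between the sexes in vehicle as in treated mice or more.

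Expression along the leading axis, from vehicle to fluoxetine, is the next pattern, where a GC or length trend is argued against as the whole cause, as 6584 of 7084 genes were still called for fluoxetine in WT females after its removal. With the bulb covariates the genes called in WT females kept 0.025% of their median change (0.39 before, with a median SE of 0.11, and 9.8e-05 after, with a median SE of 0.080). This is past the limit set against an action of fluoxetine at the same tissue make-up. However, the olfactory bulb mean was 9.13 to 10.9 in WT vehicle females and 4.07 to 7.37 in WT fluoxetine females, without overlap. The test thus rests on slopes within groups and compares no libraries of equal make-up, so such an action is not excluded. A differing share of olfactory bulb tissue in the dissected piece may account for the pattern, since the slope of each gene on the olfactory bulb mean among libraries of the same group, taken in the 10 other groups and turned in sign, correlated at 0.847 with the fluoxetine effect in WT females. Of the list's 7 genes, 4 were at 10 or more in the library with the lowest mean. The loss of calls is not particular to the bulb covariates, as nearly all calls in WT females were also lost with striatum and choroid plexus covariates. The choroid plexus mean was 4.30 to 5.19 in WT vehicle females and 3.22 to 3.75 in WT fluoxetine females, again without overlap. A differing share of choroid plexus was not tested as a cause. Whether the drug itself altered the bulb or its place in the dissection was not tested.

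Tbr1 in HT mice is the third pattern. Averaged over treatments it was 0.55 higher (SE 0.11) and with the bulb covariates 0.303 higher (SE 0.028), so a differing share of olfactory bulb tissue is argued against as the whole cause. It does not rest on 1 library, as the adjusted p with those covariates was at most 4.63e-10 when each library was left out. In vehicle mice fitted alone, with the covariates, the difference was 0.18 (adjusted p = 0.548). The allele may raise Tbr1 mRNA, a hypothesis found on these data and not tested apart from linked sequence, since the nearby genes Slc4a10, Dpp4, Fap and Ifih1 were also higher in HT mice (0.10 to 0.31).

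Single libraries lay far from the other 4 of their group in 26 of 146 tests of 13 measures. Chance gives about 1 in 20 for normally distributed values. Ddx3y in females lies near 0 and several measures follow one another, so the 26 cannot be set directly against that rate. Total reads were 31.3M in WT fluoxetine female replicate 1 and 33.98M in WT lithium female replicate 4. Mitochondrially encoded genes took 5.12% in HT fluoxetine female replicate 4 and 6.95% in HT lithium female replicate 5. The first component was at -14.9 in WT fluoxetine female replicate 5, and the second at 12.5 in HT fluoxetine male replicate 2 and -32.0 in HT vehicle female replicate 1. The olfactory bulb mean was 3.27 in HT lithium male replicate 3. The striatum mean was 10.2 in HT lithium female replicate 1, 10.4 in WT lithium female replicate 2 and 10.3 in WT lithium male replicate 2. Tbr1 was at 2241 in HT lithium male replicate 1 and 2909 in HT vehicle male replicate 2, where Eomes was at 804, and Eomes was at 117 in WT fluoxetine female replicate 5. Xist was at 248 in HT lithium male replicate 3. Ddx3y, at 0 to 0.97 in the rest of their groups, was at 6.4, 7.23 and 13.3 in replicate 5 of the HT fluoxetine, 2 of the HT lithium and 2 of the HT vehicle females, and at 0.97 and 1.05 in replicate 5 of the WT fluoxetine and of the WT vehicle females. Rps6-ps4 was at 153 in HT vehicle male replicate 5. The mitochondrial gene mt-Co1 was at 638810 in HT fluoxetine female replicate 4, 875180 in HT lithium female replicate 5, 755280 in HT lithium male replicate 3 and 875900 in WT vehicle male replicate 2.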

How the results depend on the processing

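Tests with edgeR, DESeq2 or the bulb covariates, without vehicle males or the 2 libraries with the highest olfactory bulb mean, and of HT against WT averaged over treatments were chosen after the result was seen. Of the 291 named results (a gene in a comparison), all kept their direction and side of the threshold with pseudocounts of 0.5 and 5 and with no filter. Those kept, lost, gained and turned numbered 282, 7, 0 and 2 with quantile normalization, 247, 4, 1 and 0 with the stricter filter (which tests fewer genes), 288, 3, 0 and 0 with no trend, 266, 25, 0 and 0 with only the compared groups in the fit, 206, 4, 81 and 0 with library quality weights, 269, 21, 1 and 0 with striatum and choroid plexus covariates, 283, 6, 2 and 0 with edgeR, 253, 6, 26 and 0 with DESeq2 (which gave no adjusted p for the rest), 248, 11, 32 and 0 without the 2 libraries with the highest olfactory bulb mean, 218, 39, 1 and 33 with the bulb covariates and 156, 121, 0 and 14 in females without the libraries of vehicle males. Leaving out 1 library at a time gave 7037, 163, 140 and 0. The cause was not tested for any change listed here, unless fewer samples or genes are said to be the reason. The count test set for the case of counts was not run as planned, since the table holds a signal.

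With all libraries and the limma test, genes called numbered 6 for HT against WT under vehicle, 11239 and 7249 for fluoxetine in WT and HT, 7585 and 4128 for lithium in WT and HT, 7084 and 0 for fluoxetine in WT and HT females, 1 and 3 for lithium in WT and HT females, 6559 for lithium in HT males, and 0 for both interactions of genotype with a drug. With the stricter filter genes called numbered 0 for HT against WT under vehicle. Correlations were 0.76 for fluoxetine and lithium effects in WT. With quantile normalization genes called numbered 12 for HT against WT under vehicle and 1 for lithium in HT females. Lists that passed numbered 6 for HT against WT under vehicle. Log2 fold changes were, for HT against WT under vehicle Hsp90b1 -0.028, for the genotype by lithium interaction Agap2 0.012. With no trend genes called numbered 3 for HT against WT under vehicle and 1 for lithium in HT females. With only the compared groups in the fit genes called numbered 2 for HT against WT under vehicle, 2720 for lithium in HT, 0 for lithium in WT females and 0 for lithium in HT females. Tbr1 was at 0.48 for lithium in WT, no longer called. With library quality weights genes called numbered 6987 for HT against WT under vehicle, 5139 for the genotype by fluoxetine interaction, 5160 for genotype in vehicle females, 521 for fluoxetine in HT females, 3283 for lithium in WT females, 77 for genotype in vehicle males and 434 for HT against WT averaged over treatments. Tbr1 was at 0.87 for HT against WT under vehicle and -0.53 for the genotype by fluoxetine interaction, both now called. With striatum and choroid plexus covariates genes called numbered 1 for HT against WT under vehicle, 5518 for fluoxetine in WT, 6216 for lithium in HT, 12 for fluoxetine in WT females and 3 for lithium in WT females. Tbr1 was at 0.24 for fluoxetine in WT. With a fold change of at least 1.2 genes called numbered 7071 for fluoxetine in WT, 2836 for fluoxetine in HT, 3116 for lithium in WT, 663 for lithium in HT, 1 for lithium in HT females and 4199 for lithium in HT males.

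Under the bulb covariates genes called numbered 2 for HT against WT under vehicle, 4258 for fluoxetine in WT, 4 for fluoxetine in WT females and 11 for lithium in WT females. Lists that passed numbered 4 for the genotype by fluoxetine interaction. Correlations were 0.0078 for genotype and fluoxetine effects in HT, -0.012 for genotype and lithium effects in HT, 0.67 for fluoxetine effects in WT and HT and 0.38 for fluoxetine and lithium effects in WT. Log2 fold changes were, for HT against WT under vehicle Rorb -0.0053, Th 0.070, Shisa3 0.084, Rims1 -0.044, Cplx2 -0.056, Syp -0.028, Gabbr1 -0.0026, Camk4 -0.046, Nrgn -0.085 and Fdft1 -0.020, for fluoxetine in WT Scn4b -0.27, Sebox -0.0074, Ms4a15 0.27, Frmd7 0.12, Scgn 0.19, Dnah11 0.050, Doc2g 0.20, Cdhr1 0.37 and Tbr1 -0.19, for fluoxetine in HT Eomes 0.068, Ms4a15 0.35, Cdhr1 0.17, Doc2g 0.18 and Tbr1 -0.047, for lithium in WT Tbr1 -0.080, for the genotype by fluoxetine interaction Tbr1 0.14, Doc2g -0.018, Grin2a 0.0058, Gria3 0.042, Camk2a 0.034, Rims1 0.063, Camk4 0.052, Klf9 0.017 and Nrgn 0.094, for the genotype by lithium interaction Tbr1 0.10, Hs3st4 0.011, Pclo 0.012 and Syn1 0.016. Of these, Th, Shisa3, Eomes, Cdhr1 and Doc2g are members of the list behind the covariates and balance around 0 by construction. In females without the libraries of vehicle males genes called numbered 0 for HT against WT under vehicle, 7391 for fluoxetine in WT, 0 for fluoxetine in HT, 1 for lithium in WT and 1 for lithium in HT. Lists that passed numbered 11 for fluoxetine in WT, 13 for lithium in WT, 11 for lithium in HT and 0 for the genotype by fluoxetine interaction. Log2 fold changes were, for fluoxetine in HT Dnajb9 0.0050, mt-Nd6 0.17 and mt-Nd1 0.13, for lithium in WT Tbr1 0.47, Nrxn2 -0.066, Ndufs7 -0.019, mt-Nd4l 0.0098, mt-Atp6 0.015 and mt-Nd6 0.087, for lithium in HT Nrxn2 -0.044, Ndufs7 -0.016, mt-Nd6 0.23, mt-Atp8 0.27 and mt-Atp6 0.61, for the genotype by lithium interaction Pde10a 0.12. In females without those libraries and with the bulb covariates genes called numbered 6 for fluoxetine in WT, 0 for fluoxetine in HT, 16 for lithium in WT and 2 for lithium in HT. In that fit Tbr1 was at -0.21 for fluoxetine in WT, -0.11 for lithium in WT, 0.29 for the genotype by fluoxetine interaction and 0.13 for the genotype by lithium interaction. Without the 2 libraries with the highest olfactory bulb mean genes called numbered 3734 for HT against WT under vehicle, 3230 for genotype in vehicle females and 40 for lithium in WT females. Tbr1 was at 0.84 for HT against WT under vehicle, 0.32 for lithium in WT and -0.048 for lithium in HT. With edgeR Tbr1 was at 0.41 for lithium in WT. With DESeq2 genes called numbered 1583 for HT against WT under vehicle, 2 for the genotype by fluoxetine interaction, 1 for the genotype by lithium interaction, 7 for the genotype by sex interaction under vehicle, 4 for genotype in vehicle females, 388 for fluoxetine in HT females, 38 for lithium in WT females, 7 for lithium in HT females and 3 for genotype in vehicle males. There Tbr1 was at 0.80 for HT against WT under vehicle.

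Replicate numbers are shared by all groups. Deviations from the group means correlated at 0.006 for the same number and -0.001 for other numbers, 0 of 66 pairs of groups had all 5 correlations above 0.1, and 16 of 60 libraries correlated best with their own number, so the samples share only a number. With the replicate block genes called numbered 1 for the genotype by sex interaction under vehicle and 1 for lithium in HT females. Of the named results 289 were kept with the replicate block and 2 were lost.

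By camera with an estimated correlation lists that passed numbered 0 for HT against WT under vehicle, 0 for fluoxetine in WT, 0 for fluoxetine in HT, 0 for lithium in WT, 0 for lithium in HT, 0 for the genotype by fluoxetine interaction and 0 for the genotype by lithium interaction. By fry lists that passed numbered 0 for HT against WT under vehicle, 19 for fluoxetine in WT, 12 for fluoxetine in HT, 0 for lithium in HT, 0 for the genotype by fluoxetine interaction and 0 for the genotype by lithium interaction. In females alone with the bulb covariates correlations were 0.057 for genotype and fluoxetine effects in HT, 0.38 for fluoxetine effects in WT and HT, 0.17 for lithium effects in WT and HT, 0.21 for fluoxetine and lithium effects in WT and -0.013 for fluoxetine and lithium effects in HT. With all libraries used in both contrasts correlations were 0.82 for fluoxetine and lithium effects in WT and 0.68 for fluoxetine and lithium effects in HT. In females alone genes called numbered 19 for HT against WT averaged over treatments. Correlations were 0.50 for fluoxetine and lithium effects in WT and 0.20 for fluoxetine and lithium effects in HT. In males alone genes called numbered 3 for HT against WT averaged over treatments. In vehicle mice alone genes called numbered 1 for HT against WT averaged over treatments. Its Tbr1 difference was 0.18. When each library was left out in turn, genes called ranged from 1 to 6275 for HT against WT under vehicle (6 with all), 0 to 247 in females and 0 to 1 in males (0 with all), 0 to 1 for the genotype by sex interaction under vehicle (0), 4298 to 7883 for fluoxetine in WT females (7084), 0 to 1027 for fluoxetine in HT females (0), 0 to 49 for lithium in WT females (1) and 1 to 4 for lithium in HT females (3). Tbr1 ranged from 0.66 to 1.0 for HT against WT under vehicle, 0.32 to 0.56 for lithium in WT and -0.048 to 0.23 for lithium in HT. For lithium in HT the lowest value came without replicate 1 of the HT vehicle females and the highest without replicate 1 of the HT lithium males, and the 7883 came without replicate 4 of the WT vehicle females.

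The fits without vehicle males hold fewer samples. With both that choice and the bulb covariates only counts and Tbr1 were computed. The libraries held 23930164 to 36515331 reads, so low genes carry counting error that limits small changes.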

Other observations

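The comparison of HT with WT averaged over the treatments and sexes, and all tests of it, were chosen after the data had been seen. With the bulb covariates, 174 genes passed with limma, 64 higher and 110 lower in HT mice, and 173 of them had the same sign in vehicle, fluoxetine and lithium mice. As the genes were selected by the average over these same treatments, that agreement is largely fixed in advance and is not a replication. Tbr1 was 0.30 higher (SE 0.03, adjusted p = 7.27e-11). Tshz2, a teashirt zinc finger gene (chromosome 2, 169633013 to 170071816), was 0.27 higher (SE 0.02, adjusted p = 6.53e-11), and Plcxd2, a phospholipase C domain gene, 0.29 higher (SE 0.04, adjusted p = 1.2e-06). Trhr, the receptor of thyrotropin-releasing hormone, was 0.39 higher, Mirt1 0.36, Tbx3 0.28, Mcub 0.27 and Gng11 0.25. Among lower genes were Ly6g6e (-0.51), Krt80 (-0.51), Arhgap25 (-0.48, SE 0.06, adjusted p = 7.32e-07), Ighg2c (-0.38), the Hedgehog effector Gli1 (-0.32), Cebpd (-0.30), the collagen gene Col5a1 (-0.28), Sla (-0.28) and Fancd2 (-0.24). These genes were named by size among those with a mean of at least 50. Without the covariates 215 genes passed, 79 of them in both sets. Of the genes named here, Mcub turned without them (-0.039), and Trhr (0.25), Gng11 (0.18), Krt80 (-0.19), Arhgap25 (-0.22), Sla (-0.071) and Fancd2 (-0.17) were not called. Females alone gave 19, males alone 3 and vehicle mice alone 1, fits with fewer samples. Treated mice alone gave 148, and 156 passed in all libraries but the vehicle males. In vehicle mice alone Tbr1 was at 0.18, Tshz2 at 0.14 and Plcxd2 at 0.16, none called. In treated mice alone they were at 0.35, 0.32 and 0.35, all called. In males alone Plcxd2 was not called (0.26, limma adjusted p = 0.151), while Tbr1 (0.36) and Tshz2 (0.27) were. Leaving out 1 library gave 124 to 221. Regrouping genotypes within treatment and sex gave as many in 1 of 100 splits, the real one, with 3 as the highest other, so chance is unlikely. The splits do not cover shared litters or the choice of comparison and covariates, which was made after the data had been seen.

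Of the genes near Tbr1, 4 were higher in HT mice as well. Within 5 Mb of Tbr1 on chromosome 2, a window chosen after the values were seen, 4 of 41 other tested genes passed, all higher, against 15 of 1327 elsewhere on that chromosome and 154 of 16401 on other chromosomes. They were the neighbours Slc4a10 (62046462 to 62326730, 0.10 higher), Dpp4 (62330073 to 62412231, 0.31), Fap (62500943 to 62574075, 0.31) and Ifih1 (62595798 to 62646255, 0.21), in that order on the chromosome (GRCm38). Their adjusted p-values from limma were 0.0097, 0.0091, 0.0015 and 0.0024.

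Other splits of the libraries were counted, 100 for each comparison with the real one. For HT against WT under vehicle, 6 of 100 splits gave 6 genes or more, up to 3469, so chance cannot be excluded, and such a split points to a structure of the samples, whose cause was not tested. Chance is unlikely for fluoxetine in WT (11239 genes, highest other 6781) and HT (7249, 2112) and lithium in WT (7585, 6807), each with 1 of 100 splits as large. For lithium in HT (4128) 2 of 100 were as large, under the limit of 5. The highest other gave 4401 there, so chance is less likely but not excluded. The splits exchange single libraries and do not cover litters that share a treatment. Chance is also unlikely, with 1 of 100, for the interactions of sex with fluoxetine (7029, 1688) and lithium (7251, 470) and for fluoxetine in WT females (7084, 5284). The same holds in males for fluoxetine in WT (10316, 8091) and HT (7356, 4297) and lithium in WT (8571, 6645) and HT (6559, 4301). The male and averaged comparisons follow the vehicle male cluster, so this does not separate drug from batch. For lithium in WT females (1 gene) 10 of 100 splits gave as many, up to 6698, and in HT females (3 genes) 5 of 100, up to 2189, so chance cannot be excluded. Where 0 genes were called, 100 of 100 splits gave as many by definition. The highest other was 1 for genotype by fluoxetine, 6763 for genotype by lithium, 5895 for genotype by sex, 6756 and 4678 for genotype in females and males, and 0 for fluoxetine in HT females. The high counts among these point to a structure of the samples as well.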
